A study of Caenorhabditis elegans with 36 samples.

How the data were processed

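The deposited table held raw counts per gene for 36 libraries and 27782 gene identifiers, and the counts were used as the authors deposited them. Per the submitters' processing notes, reads from a BGISEQ-500 were checked with FastQC and aligned to WBcel235 with STAR 2.7.3a, and the authors' own comparisons used DESeq2 1.40.2. The counting tool, the strandedness and the annotation release were not given in the sources used here. Per the labels, RNA was extracted with TriPure and columns, and each group had 4 biological replicates. Names came from a reference table for 25676 identifiers and sequence names for 1887 more.

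The comparisons, alternatives, gene lists and rule for naming genes were fixed before the data were examined. Genes were kept by edgeR's filterByExpr with a minimum count of 10, and libraries were scaled by TMM. Each batch was fitted as a whole with edgeR 4.0.16 in R 4.3.3 (robust dispersions, quasi-likelihood F test), and all groups of a batch shared one fit. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Differences of effects between batches used one fit with batch and treatment as terms. DESeq2 1.42.0 was the second tool. SEs were derived from the log2 fold change and the F statistic.

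Genes named in the text were the 8 largest rises and 8 largest falls with a gene symbol, an adjusted p below 0.05, a mean of at least 5 CPM in a group and all 4 libraries of a group apart from the other group's. To these came 2 rises and 2 falls with a sequence name, a fixed panel of stress genes, and up to 4 members of each list by smallest p. Direct contrasts, differences and the DMSO comparison used 5 rises and 5 falls. Where a group had 3 counts or fewer, a ratio with a 95% counting interval is given, or for 0 counts a bound against a floor of 3 counts over the 4 libraries.

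There were 33 gene lists, 8 of them tissue or stage markers, compiled from general knowledge. They were tested with camera of limma 3.58.1 with a preset correlation between genes of 0.01, and again with an estimated correlation. A further test, fry of limma, asks whether a list moved at all and not whether it moved relative to other genes. P-values were adjusted separately over the lists of the comparisons with DMSO, of the direct contrasts and of the differences of effects. Member counts adjusted over the list alone are given beside those over all genes. The names hsp-16.11, hsp-16.49, daf-21, T24B8.5, F35E12.5, F26F2.2, sqrd-2, vet-4, vet-5, opt-2 and ndfl-4 could not be matched to the table, of which T24B8.5 and F35E12.5 are older names of sysm-1 and irg-5, which were in their list.

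The fits had no replicate term, a choice made beforehand. No 2 libraries of a group were near-identical, the lowest chi-square per degree of freedom being 4.42.

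The procedure was tried on simulated counts in which 200 genes were changed, 50 at each of 0.5, 1, 2 and 3 on the log2 scale. For the terbinafine design 56%, 78%, 100% and 98% were recovered, with 5.68% of calls false. For the doxycycline design these were 24%, 56%, 86% and 98%, with 7.69% false, above the nominal 5%. The difference of effects gave 24%, 52%, 76% and 94% with 6.11% false, and the DMSO comparison 24%, 52%, 94% and 90% with 5.11% false. A list of 30 genes raised by 0.5 was found in both designs, and an unchanged one was not. The simulated counts were drawn for each gene independently. This therefore does not test false calls for lists whose genes vary together, as those of many real lists did.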

Results

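Whole-worm RNA-seq was carried out on Caenorhabditis elegans of the wild-type strain N2, in a study of mitochondrial stress responses that centred on terbinafine, an antifungal drug that inhibits squalene epoxidase, and miglustat, an iminosugar that inhibits glucosylceramide synthase. The worms were exposed from the first larval stage and collected as adults of day 1, about 3000 worms per sample, at 20 °C and with 10 µM 5-fluorouracil on the plates. There were 36 libraries in 9 groups of 4 biological replicates. Batch 1 held 24 libraries in 6 groups: DMSO, the solvent control; terbinafine at 31.5 µM; miglustat at 250 µM; BAY2402234 at 500 µM; brequinar at 500 µM; and worms fed bacteria that express dhod-1 double-stranded RNA. Batch 2 held 12 libraries in 3 groups: DMSO, doxycycline at 50 µM and teriflunomide at 250 µM. Per the labels, the dhod-1 RNAi worms also received DMSO. All other groups are marked ev, read here as the empty vector of RNAi feeding. BAY2402234, brequinar and teriflunomide are inhibitors of dihydroorotate dehydrogenase, the mitochondrial enzyme of pyrimidine synthesis that dhod-1 encodes, and doxycycline is an antibiotic that also blocks mitochondrial translation. Total counts per library lay between 19253276 and 20455600.

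Every treatment was compared with the DMSO libraries of its own batch, over 15142 genes in batch 1 and 15695 genes in batch 2. Expression is given as mean CPM (counts scaled by library size) ± SD over n = 4 libraries, and changes as log2 fold changes with their standard error (SE). A gene or list is said to have risen, fallen or changed only where its Benjamini-Hochberg adjusted p was below 0.05, by edgeR's quasi-likelihood test for genes and by camera for lists. The first principal component of all 36 libraries held 62.9% of the variance over 9458 genes and set the 4 doxycycline libraries apart; the second held 14.6%. Along the second, replicate 1 of the batch 2 DMSO group lay at -32.6 and the other 3 between -9.43 and 5.86, while the dhod-1 RNAi replicates 3 and 4 lay at 63.8 and 80.7 and replicates 1 and 2 at 37.3 and 35.5.

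**Figure D1:**
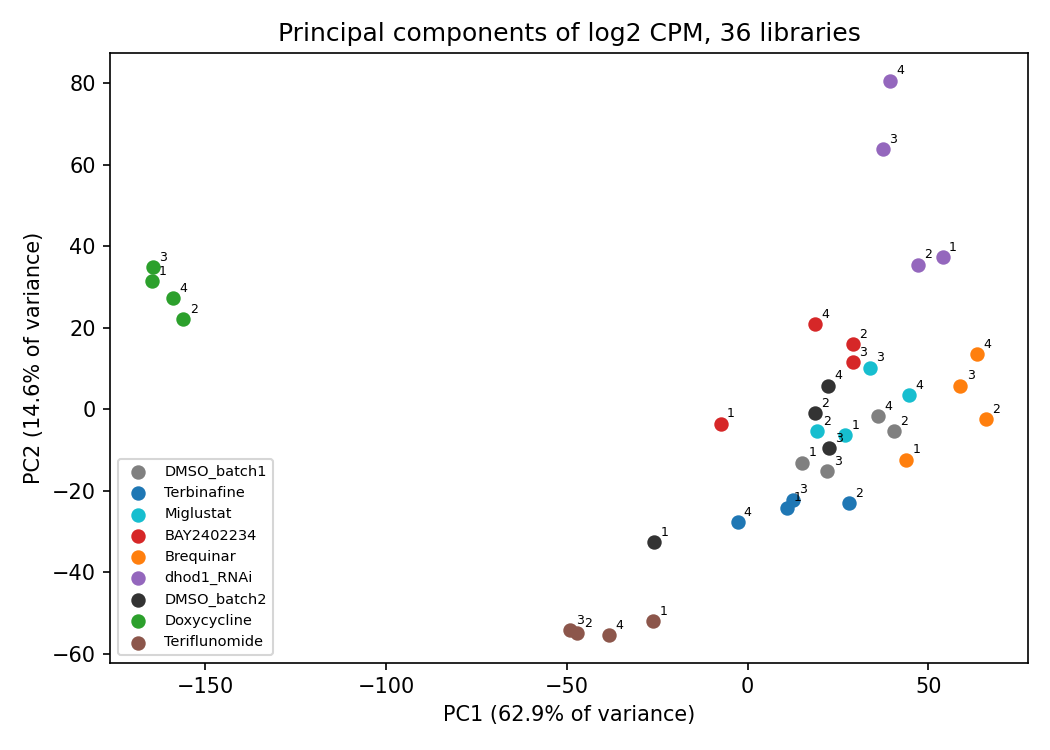
Principal components 1 and 2 of log2 CPM over 9458 genes, 1 point per library, coloured by group and marked with the replicate number; the axes give the component scores with 62.9% and 14.6% of the variance. Doxycycline lies at the far left, dhod-1 RNAi replicates 3 and 4 lie above replicates 1 and 2, and replicate 1 of the batch 2 DMSO group lies nearest to teriflunomide.

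The knocked-down gene itself was examined first. dhod-1 (WBGene00020932; chromosome I, 6736680 to 6741176, build WBcel235) stood at 58.1, 78.5, 68.2 and 70.8 CPM in the 4 dhod-1 RNAi libraries, against 82.7, 79.8, 90.3 and 81.4 CPM in the batch 1 DMSO libraries. The arithmetic means were 68.9 and 83.5 CPM. The mean of the log2 values was lower by 17.9% on the linear scale, and a two-sided exact permutation test of these gave p = 0.0286, the smallest that 4 against 4 libraries can give. In the fit of all genes the log2 fold change was -0.28 (SE 0.08, edgeR adjusted p = 0.00482). dhod-1 also fell with BAY2402234, by -0.44 (SE 0.08, edgeR adjusted p = 0.000249), and with doxycycline, by -0.60 (SE 0.08, edgeR adjusted p = 1.2e-05). Reads from the double-stranded RNA itself cannot be told from those of the worm's own transcript in these counts.

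**Figure D2:**
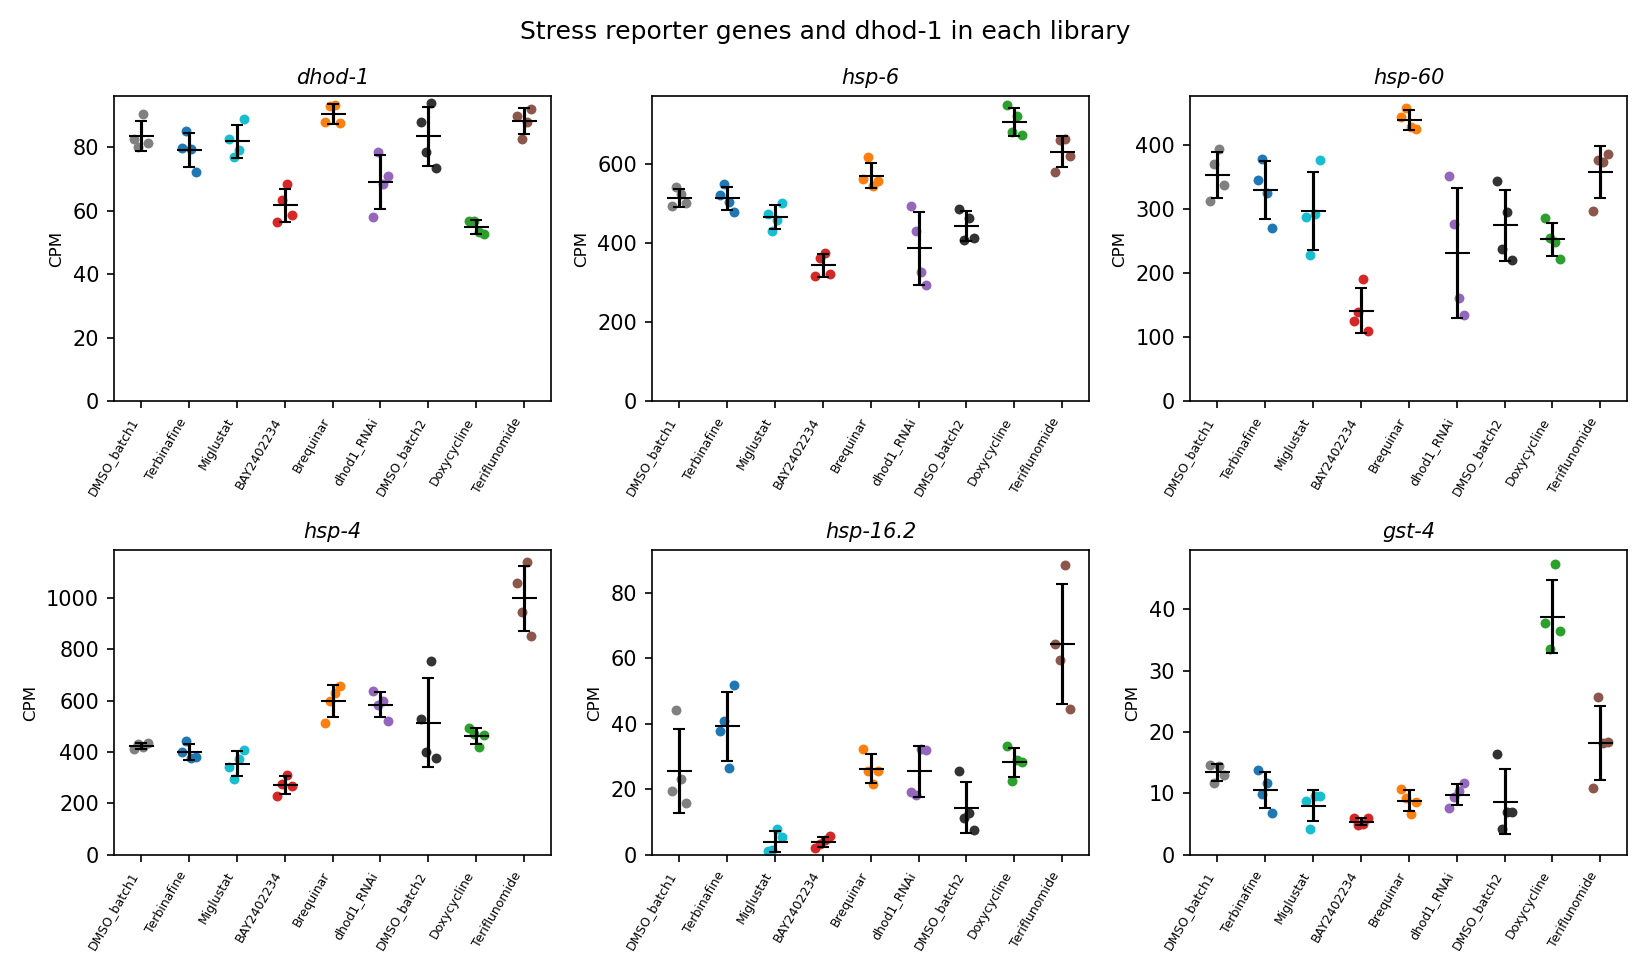
CPM of dhod-1, hsp-6, hsp-60, hsp-4, hsp-16.2 and gst-4 in each library (points) with the mean ± SD of each group (n = 4), on axes that start at 0. hsp-6, a mitochondrial Hsp70, averaged 705.5 CPM with doxycycline and 630.8 CPM with teriflunomide against 442.9 CPM in DMSO of batch 2, and 343.7 CPM with BAY2402234 against 514.7 CPM in DMSO of batch 1.

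Terbinafine changed few genes, and the largest changes were rises of cytochrome P450 genes, which encode enzymes that oxidise foreign compounds. The neighbouring genes cyp-35B2 and cyp-35B3 (chromosome V, 3942160 to 3944523 and 3945353 to 3947044) went from 2 and 1 counts over the 4 DMSO libraries to 579.3 ± 201 and 462.5 ± 84.7 CPM. The ratios were 22700 (95% counting interval 6280 to 187000) and 36200 (6490 to 1430000). cyp-35B1 rose from 0.576 ± 0.0889 to 67.2 ± 23.6 CPM, cyp-35A1 from 0.14 ± 0.111 to 34.7 ± 19.8 CPM, and the transporter gene pgp-13 from 2.92 ± 0.855 to 187.8 ± 37.4 CPM (edgeR adjusted p = 1.58e-14). cyp-33C6 rose by 7.45, C01G12.5 by 9.90 and R05D8.9 by 7.02 (edgeR adjusted p = 6.67e-13, 2.77e-15 and 2.33e-05). Among the falls were sysm-1, an immune reporter gene (-1.66, SE 0.24, edgeR adjusted p = 0.000459), the C-type lectin gene clec-48 (-1.42, SE 0.20, edgeR adjusted p = 0.000303) and oac-20 (-1.62, SE 0.27, edgeR adjusted p = 0.00145). Of 28 innate immunity genes, 2 fell and 0 rose (5 and 1 adjusted over the list alone, adjusted p = 0.559 with an estimated correlation).

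By edgeR, 136 genes changed with terbinafine, 103 higher and 33 lower, of which 57 and 23 by at least 2-fold. Of 162 xenobiotic enzyme genes tested, 16 rose and 0 fell (26 and 3 adjusted over the list alone), with adjusted p = 0.512 with an estimated correlation. At an unadjusted p below 0.05, 2002 of the 15142 genes passed. Of 13 hypoxia and hydrogen sulfide response genes, 3 rose and 0 fell (7 and 0 adjusted over the list alone), and the list's rise held with an estimated correlation (camera adjusted p = 0.0296). Its members cysl-2, a cysteine synthase-like gene, and phy-2, a collagen prolyl hydroxylase gene, rose by 0.70 (SE 0.10, edgeR adjusted p = 0.000147) and 1.15 (SE 0.17, edgeR adjusted p = 0.000519). The 10 genes of mitochondrial DNA that were tested moved together, with 6 lower and 0 higher (10 and 0 adjusted over the list alone) and a median of -0.66. The camera adjusted p was 1.66e-20, and adjusted p = 0.059 with an estimated correlation. ctc-2 and ctb-1, subunits of cytochrome c oxidase and of the bc1 complex, fell by -0.69 (SE 0.11, edgeR adjusted p = 0.00141) and -0.62 (SE 0.11, edgeR adjusted p = 0.00261). These genes took 0.203% ± 0.0226 of all counts with terbinafine and 0.301% ± 0.0284 in DMSO. hsp-6 and hsp-60, chaperone genes of the mitochondrial unfolded protein response, did not pass, at -0.00 (SE 0.11, edgeR adjusted p = 0.997) and -0.10 (SE 0.22, edgeR adjusted p = 0.917). Of 34 fatty acid oxidation genes, 3 rose and 0 fell (7 and 1 adjusted over the list alone, adjusted p = 0.559 with an estimated correlation). The call for the list fatty acid oxidation in Terbinafine vs DMSO_batch1, camera adjusted p = 0.0153 by limma, was lost without DMSO replicate 2 (0.076). The peroxisomal oxidase gene acox-3 rose by 0.90 (SE 0.17, edgeR adjusted p = 0.00595), and gst-5 by 2.33 (SE 0.35, edgeR adjusted p = 0.000654). Sperm genes took 0.0767% ± 0.0309 of the counts against 0.0353% ± 0.0149 in DMSO, and none of the 52 tested passed edgeR's test (0 adjusted over the list alone, adjusted p = 0.559 with an estimated correlation). Of 134 cuticle collagen genes, 0 passed edgeR's test (9 rose adjusted over the list alone, median 0.92, camera adjusted p = 0.512 with an estimated correlation). Of 15 molting larva genes, 1 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.53, camera adjusted p = 0.559 with an estimated correlation). DESeq2 called 243 genes in place of 136, and without DMSO replicate 4 or terbinafine replicate 4 edgeR called 87 and 76. Reads of the near-identical cyp-35B copies may be divided wrongly between them, so their single values are uncertain.

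Miglustat lowered heat shock genes. hsp-70 (chromosome I, 9320325 to 9322519), an inducible cytosolic Hsp70 gene, fell from 33.2 ± 20.4 to 3.91 ± 2.68 CPM, a log2 fold change of -3.09 (SE 0.44, edgeR adjusted p = 0.00293). The small heat shock genes hsp-16.2, hsp-16.48 and hsp-17 fell by -2.67, -2.36 and -1.43 (edgeR adjusted p = 0.00692, 0.00598 and 0.00391), and unc-23, a BAG-family cochaperone gene, by -1.08 (SE 0.17, edgeR adjusted p = 0.00391). Of 16 cytosolic heat shock genes tested, 9 fell and 0 rose (13 and 0 adjusted over the list alone), the median was -1.97, and the list's fall held with an estimated correlation (camera adjusted p = 0.00158). The members F44E5.4 and F44E5.5, of the Hsp70 family, fell by -2.66 (SE 0.35) and -2.47 (SE 0.33), both with an edgeR adjusted p of 0.000988. The copies of hsp-16 genes are near-identical, so how their reads were divided is uncertain.

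In all, edgeR found 88 genes changed with miglustat, 66 higher and 22 lower (36 and 15 by at least 2-fold). The largest rises that held with any 1 library left out included gst-22, a glutathione S-transferase gene (1.51, SE 0.27, edgeR adjusted p = 0.00714), thn-2, a thaumatin-family gene (1.37, SE 0.23, edgeR adjusted p = 0.00648), and F53F1.6 (1.88, SE 0.30, edgeR adjusted p = 0.00437). Y94H6A.10 and F19B2.5 fell by -1.79 (SE 0.28, edgeR adjusted p = 0.00437) and -1.59 (SE 0.24, edgeR adjusted p = 0.00391). Of 13 targets of DAF-16, the transcription factor of insulin signalling, 0 passed edgeR's test over all genes and 6 rose adjusted over the list alone, where 1438 of 15142 genes had an unadjusted p below 0.05. The list's median was 0.57, and its rise held with an estimated correlation (camera adjusted p = 0.0364). lys-7 and icl-1, a lysozyme gene and a glyoxylate cycle gene, stood at 1.29 (SE 0.31, edgeR adjusted p = 0.0654) and 0.82 (SE 0.22, edgeR adjusted p = 0.102). DESeq2 gave adjusted p = 0.00612 for lys-7 in Miglustat vs DMSO_batch1 and 0.023 for icl-1 in Miglustat vs DMSO_batch1, and without miglustat replicate 4 edgeR gave 0.0215 for lys-7. Of 34 fatty acid oxidation genes, 4 rose and 0 fell (9 and 0 adjusted over the list alone), with adjusted p = 0.404 with an estimated correlation. The peroxisomal oxidase gene acox-3 rose by 1.05 (SE 0.17, edgeR adjusted p = 0.00473). Of 30 sphingolipid genes, the pathway in which miglustat acts, 1 rose and 0 fell (1 and 0 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0847). The call for the list sphingolipid metabolism in Miglustat vs DMSO_batch1 was gained by camera of limma without DMSO replicate 1 (adjusted p = 0.0435) or miglustat replicate 2 (0.0474). Tissue marker lists moved by camera with the preset correlation, but hardly gene by gene, and no such call held with an estimated correlation. Of 52 sperm genes and 23 muscle genes, 0 passed edgeR's test (0 adjusted over either list alone), with medians of -0.62 and -0.23 and falls by camera at adjusted p = 2.69e-08 and 5.69e-08. These gave adjusted p = 0.599 and adjusted p = 0.558 with an estimated correlation. Of 39 zygotic embryo genes, 1 rose and 0 fell (3 and 0 adjusted over the list alone, median 0.34, adjusted p = 0.512 with an estimated correlation). None of 38 germ line genes passed (0 adjusted over the list alone, median -0.09, adjusted p = 0.785 with an estimated correlation). The call for the list oocyte and germ line in Miglustat vs DMSO_batch1, camera adjusted p = 0.00387 by limma, was lost without miglustat replicate 2 (0.0838). hsp-6, at 466 ± 30 against 514.7 ± 22.4 CPM, did not change (edgeR adjusted p = 0.812). Without miglustat replicate 4 edgeR called 254 genes, without DMSO replicate 2 or 3 it called 22 and 33, without miglustat replicate 2 it called 25, and DESeq2 called 270. Fitted with the DMSO group alone the count was 39, and with the stricter filter 51.

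Terbinafine and miglustat, compared with each other, differed in 448 genes by edgeR, 218 higher and 230 lower with terbinafine. Heat shock genes were higher with terbinafine, 9 of 16 (11 adjusted over the list alone) with a median of 2.86 (camera adjusted p = 0.0032 with an estimated correlation). The mitochondrial DNA genes were lower with terbinafine, 9 of 10 (10 adjusted over the list alone) with a median of -0.89 (camera adjusted p = 0.0236 with an estimated correlation). Of 52 sperm genes, 3 were higher with terbinafine (48 adjusted over the list alone, median 1.74, adjusted p = 0.475 with an estimated correlation), and of 134 cuticle collagen genes, 13 (64 adjusted over the list alone, median 0.91, adjusted p = 0.475 with an estimated correlation). Of 39 zygotic embryo genes, 1 was lower (1 adjusted over the list alone, median -0.36, adjusted p = 0.48 with an estimated correlation). None of 23 muscle genes passed edgeR's test (0 adjusted over the list alone, median 0.25, adjusted p = 0.48 with an estimated correlation). gst-22 was lower by -1.94 (SE 0.28, edgeR adjusted p = 0.000141) and dod-22 by -2.05 (SE 0.38, edgeR adjusted p = 0.00255). The fold changes against their shared DMSO libraries had a Pearson correlation of 0.112 and a Spearman correlation of 0.124 across genes, which are not independent replicates, and a covariance of 0.0218. Groups simulated with no effect gave 0.501 and a covariance of 0.0525 from the shared controls. With the controls split 2 and 2 the correlation was -0.034. Both compounds raised 6 genes, against 0.4 for independent lists. DESeq2 called 863 genes and the stricter filter 246. edgeR called 241 without miglustat replicate 3, and 213 and 287 without terbinafine replicates 1 and 3.

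BAY2402234 changed 7088 genes by edgeR, 3519 higher and 3569 lower, of which 1490 and 150 by at least 2-fold. The median of all genes was 0.105, and 0.117 with DESeq2's size factors. adh-1, an alcohol dehydrogenase gene (chromosome V, 11888248 to 11889650), rose from 100.8 ± 34.9 to 985.9 ± 147 CPM, a log2 fold change of 3.29 (SE 0.46, edgeR adjusted p = 3.42e-05). pals-31 rose by 3.98 (SE 0.42, edgeR adjusted p = 1.39e-06), ugt-18 by 3.63 (SE 0.57, edgeR adjusted p = 9.12e-05) and clec-70 by 4.96 (SE 0.82, edgeR adjusted p = 0.00013). Yolk protein genes split: vit-1, vit-3 and vit-4 fell by -3.19, -2.63 and -2.33 (edgeR adjusted p = 4.28e-07, 2.22e-06 and 2.61e-06), while vit-2 rose by 0.33 (SE 0.10, edgeR adjusted p = 0.00782). The other 2 of the 6 yolk genes did not pass. Together the 6 took 9.413% ± 1.15 of the counts against 8.475% ± 0.281 in DMSO. How reads were divided among similar yolk genes is uncertain. The folate transporter gene folt-2 fell from 233.7 ± 16 to 26.2 ± 20.5 CPM (-3.16, SE 0.61, edgeR adjusted p = 0.000541).

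Mitochondrial and cytosolic chaperones fell with BAY2402234. Of 20 mitochondrial unfolded protein response genes, 15 fell and 1 rose (15 and 1 adjusted over the list alone), with adjusted p = 0.512 with an estimated correlation. hsp-6 fell by -0.58 (SE 0.11, edgeR adjusted p = 0.000389), hsp-60 by -1.33 (SE 0.22, edgeR adjusted p = 0.000162), and phb-1 and phb-2, the prohibitin genes, by -0.71 and -0.69. Of 16 cytosolic heat shock genes, 15 fell and 0 rose (15 and 0 adjusted over the list alone, adjusted p = 0.0842 with an estimated correlation), and hsp-70 fell from 33.2 to 2.88 ± 0.933 CPM. Proteasome genes fell in 31 of 33 cases (33 adjusted over the list alone, median -0.62, adjusted p = 0.512 with an estimated correlation), and mitochondrial ribosome genes in 61 of 69 (63 adjusted over the list alone, adjusted p = 0.512 with an estimated correlation). Defence genes rose. Of 28 innate immunity genes, 22 rose and 1 fell (22 and 1 adjusted over the list alone, adjusted p = 0.301 with an estimated correlation), with sysm-1 at 2.09 (SE 0.23, edgeR adjusted p = 2.61e-06) and lys-8 at 1.57 (SE 0.17, edgeR adjusted p = 2.61e-06). Of 28 genes of the intracellular pathogen response, 20 rose and 0 fell (21 and 1 adjusted over the list alone, adjusted p = 0.512 with an estimated correlation). Of 13 DAF-16 targets, 9 rose and 0 fell (9 and 0 adjusted over the list alone), and this list held with an estimated correlation (camera adjusted p = 0.0296). aqp-1, an aquaporin gene, rose by 1.94 (SE 0.21, edgeR adjusted p = 2.61e-06) and icl-1 by 1.67 (SE 0.23, edgeR adjusted p = 1.95e-05). Tissue markers moved too. Neuron genes rose in 23 of 68 cases with 0 lower (21 and 0 adjusted over the list alone, adjusted p = 0.599 with an estimated correlation), and intestine genes in 10 of 18 with 2 lower (10 and 2 adjusted over the list alone, adjusted p = 0.599 with an estimated correlation). Zygotic embryo genes rose in 14 of 39 with 1 lower (12 and 1 adjusted over the list alone, median 0.38, camera adjusted p = 0.612 with an estimated correlation). Of 38 oocyte and germ line genes, 26 fell and 0 rose (30 and 0 adjusted over the list alone, adjusted p = 0.599 with an estimated correlation), and these genes took 2.04% ± 0.0257 of the counts against 2.52% ± 0.061 in DMSO.

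Brequinar, at the same 500 µM, changed 2370 genes by edgeR, 762 higher and 1608 lower (212 and 671 by at least 2-fold). pgp-1, a transporter gene expressed in the intestine, rose from 3.5 ± 1.68 to 71.4 ± 52.6 CPM (4.35, SE 0.41, edgeR adjusted p = 2.9e-06), and irg-5, an infection response gene, from 73.8 ± 6.21 to 462 ± 20.4 CPM (2.65, SE 0.24, edgeR adjusted p = 2.9e-06). gba-2, a glucosylceramidase gene, rose by 4.74 (SE 0.66, edgeR adjusted p = 8.87e-05) and acdh-2, an acyl-CoA dehydrogenase gene, by 3.12 (SE 0.29, edgeR adjusted p = 2.47e-06). cyp-13A6 had 3 counts over the DMSO libraries, and its ratio was 59 (95% counting interval 19.9 to 289). Collagen genes of the cuticle led the falls, with col-81 at -3.23 (SE 0.45, edgeR adjusted p = 9.03e-05), col-129 at -3.01 (SE 0.40, edgeR adjusted p = 6.31e-05) and col-139 at -2.92 (SE 0.38, edgeR adjusted p = 5.08e-05).

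Of 134 cuticle collagen genes tested with brequinar, 20 fell and 6 rose (22 and 6 adjusted over the list alone, adjusted p = 0.65 with an estimated correlation). Muscle genes fell, 19 of 23 (22 lower and 1 higher adjusted over the list alone, median -0.63, adjusted p = 0.303 with an estimated correlation). The myosin light chain genes mlc-1 and mlc-3 fell by -0.75 (SE 0.10, edgeR adjusted p = 5.08e-05) and -0.63 (SE 0.10, edgeR adjusted p = 0.000277). Of 39 zygotic embryo genes, 16 rose and 0 fell (24 and 2 adjusted over the list alone, adjusted p = 0.282 with an estimated correlation), among them vet-6 at 1.07 (SE 0.21, edgeR adjusted p = 0.00134). Sperm genes fell in 19 of 52 cases (47 adjusted over the list alone, adjusted p = 0.559 with an estimated correlation), and they took 0.0109% ± 0.0058 of the counts against 0.0353% ± 0.0149 in DMSO. Of 17 endoplasmic reticulum stress genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone, adjusted p = 0.559 with an estimated correlation). The call for the list ER UPR in Brequinar vs DMSO_batch1, camera adjusted p = 0.0176 by limma, was lost without brequinar replicate 4 (0.0572). hsp-4, the BiP gene of the endoplasmic reticulum, rose by 0.50 (SE 0.10, edgeR adjusted p = 0.00161), and pdi-6, a protein disulfide isomerase gene, by 0.48 (SE 0.12, edgeR adjusted p = 0.00881). Of 17 pyrimidine genes, 2 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.07, camera adjusted p = 0.0442, adjusted p = 0.512 with an estimated correlation). tyms-1 and rnr-2, for thymidylate synthase and a ribonucleotide reductase subunit, rose by 0.54 (SE 0.09, edgeR adjusted p = 0.000289) and 0.41 (SE 0.10, edgeR adjusted p = 0.00638), and dpyd-1 fell by -0.50 (SE 0.15, edgeR adjusted p = 0.0259). The edgeR call for dpyd-1 in Brequinar vs DMSO_batch1 was lost without DMSO replicates 1 or 4 (0.105 and 0.0509) or brequinar replicates 2 or 3 (0.0798 and 0.0562). The call by camera of limma for the list pyrimidine metabolism in Brequinar vs DMSO_batch1 was lost without DMSO replicates 1, 2 or 3 (0.0534, 0.0766 and 0.062) or brequinar replicates 2 or 3 (0.063 and 0.0526). Of 20 mitochondrial unfolded protein response genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.332), and hsp-6 stood at 0.15 (SE 0.11, edgeR adjusted p = 0.379). edgeR called 1154 and 1500 genes without DMSO replicates 1 and 3, and 1321 and 1393 without brequinar replicates 3 and 4. With only these groups fitted it called 3749, of which 42.7% were higher against 32.2% in the fit of the whole batch, and with no filter 21.3% of 1712 were higher.

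The dhod-1 RNAi libraries differed from DMSO in 9295 genes by edgeR, 4734 higher and 4561 lower (2606 and 812 by at least 2-fold). cutl-2, a cuticlin-like gene, rose from 0.167 ± 0.0781 to 11.3 ± 3.49 CPM (6.03, SE 0.64, edgeR adjusted p = 1.57e-07). dpy-14, a collagen gene, rose from 8.55 ± 4.13 to 266.9 ± 81.8 CPM (4.96, SE 0.57, edgeR adjusted p = 6.66e-07), and hch-1, a hatching protease gene, from 1.51 ± 0.722 to 92.8 ± 36.1 CPM (5.93, SE 0.67, edgeR adjusted p = 5.95e-07). cyp-13B1 rose by 5.00 (SE 0.49, edgeR adjusted p = 1.22e-07). Of 134 cuticle collagen genes, 63 fell and 23 rose (64 and 23 adjusted over the list alone, median -0.99, adjusted p = 0.77 with an estimated correlation). The call for the list cuticle collagens in dhod1_RNAi vs DMSO_batch1, camera adjusted p = 0.00642 by limma, was lost without dhod-1 RNAi replicate 1 (0.0615). Among the falls were col-81 at -4.54 (SE 0.49, edgeR adjusted p = 3.35e-07) and col-129 at -4.04 (SE 0.43, edgeR adjusted p = 2.49e-07).

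Endoplasmic reticulum stress genes rose with dhod-1 RNAi, 12 of 17 with 1 lower (12 and 1 adjusted over the list alone, median 0.55, adjusted p = 0.301 with an estimated correlation). Among them were dnj-27 at 1.61 (SE 0.14, edgeR adjusted p = 3.2e-08), pdi-6 at 1.37 (SE 0.12, edgeR adjusted p = 3.72e-08) and hsp-3, a BiP gene, at 1.12 (SE 0.11, edgeR adjusted p = 8.13e-08). Cytosolic ribosome genes fell, 77 of 81 with 1 higher (77 and 2 adjusted over the list alone, median -0.78, adjusted p = 0.512 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes fell in 40 of 48 cases with 3 higher (40 and 3 adjusted over the list alone, adjusted p = 0.559 with an estimated correlation), and mitochondrial unfolded protein response genes in 14 of 20 with 1 higher (14 and 1 adjusted over the list alone, adjusted p = 0.559 with an estimated correlation). hsp-6 fell by -0.41 (SE 0.11, edgeR adjusted p = 0.00287), and its fall is largest in the replicates that stand apart, with 493.2, 431, 325.5 and 294.9 CPM in replicates 1 to 4 against 492.7 to 541 CPM in DMSO. Of the pyrimidine genes 6 rose and 6 fell of 17 (6 and 6 adjusted over the list alone, camera adjusted p = 0.977), tyms-1 by 0.92 and rnr-2 by 0.94 (edgeR adjusted p = 7.24e-08 and 1.46e-07). Zygotic embryo genes rose in 25 of 39 cases with 1 lower (25 and 1 adjusted over the list alone, adjusted p = 0.559 with an estimated correlation), and molting larva genes in 10 of 15 with 2 lower (10 and 2 adjusted over the list alone, adjusted p = 0.559 with an estimated correlation). Muscle genes fell in 20 of 23 with 1 higher (20 and 1 adjusted over the list alone, adjusted p = 0.559 with an estimated correlation), and intestine genes rose in 9 of 18 with 0 lower (9 and 0 adjusted over the list alone, adjusted p = 0.599 with an estimated correlation). Sperm genes fell in 48 of 52 cases with 2 higher (49 and 2 adjusted over the list alone, adjusted p = 0.563 with an estimated correlation) and took 0.00514% ± 0.00196 of the counts against 0.0353% ± 0.0149. Germ line genes fell in 35 of 38 with 1 higher (36 and 1 adjusted over the list alone, adjusted p = 0.599 with an estimated correlation) and took 1.84% ± 0.535 against 2.52% ± 0.061. That share was 2.23%, 2.34%, 1.57% and 1.22% in replicates 1 to 4, so replicates 3 and 4 carry most of the difference. Replicates 1 and 2 of this group alone gave 5132 genes, a choice made after seeing the data. For hsp-60 in dhod1_RNAi vs DMSO_batch1, which fell by -0.61, the edgeR adjusted p was 0.0209. That call was lost without DMSO replicate 3 (0.0523) or dhod-1 RNAi replicates 3 (0.0864) or 4 (0.0951).

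BAY2402234 and brequinar were both given at 500 µM, and compared directly they differed in 9598 genes by edgeR, 5021 higher and 4577 lower with BAY2402234 (3064 and 268 by at least 2-fold). The median of all genes was 0.156. adh-1 was higher by 5.15 (SE 0.51, edgeR adjusted p = 9.86e-08), dod-22 by 5.50 (SE 0.44, edgeR adjusted p = 7.18e-09) and pals-31 by 5.01 (SE 0.46, edgeR adjusted p = 2.01e-08). pgp-1 was lower by -4.47 (SE 0.41, edgeR adjusted p = 4.27e-08), hsp-70 by -3.97 (SE 0.46, edgeR adjusted p = 6.38e-07) and acdh-2 by -3.63 (SE 0.30, edgeR adjusted p = 7.12e-09). DAF-16 targets were higher with BAY2402234, 12 of 13 (12 adjusted over the list alone, median 2.29, camera adjusted p = 0.0113 with an estimated correlation). Proteasome genes were lower in 32 of 33 cases (33 adjusted over the list alone, adjusted p = 0.475 with an estimated correlation), and mitochondrial unfolded protein response genes were lower in 16 of 20 and higher in 2 (16 and 2 adjusted over the list alone, adjusted p = 0.48 with an estimated correlation). Tissue markers differed as well. Neuron genes were higher with BAY2402234 in 51 of 68 cases (51 adjusted over the list alone, adjusted p = 0.555 with an estimated correlation), sperm genes in 43 of 52 (48 adjusted over the list alone, adjusted p = 0.822 with an estimated correlation) and muscle genes in 15 of 23 (15 adjusted over the list alone, adjusted p = 0.56 with an estimated correlation). Intestine genes were higher in 12 of 18 and lower in 3 (13 and 3 adjusted over the list alone, adjusted p = 0.56 with an estimated correlation), and germ line genes lower in 34 of 38 (34 adjusted over the list alone, adjusted p = 0.56 with an estimated correlation). The sperm share was 0.0975% in BAY2402234 replicate 1 and 0.0196% to 0.0235% in the other 3, so that replicate carries much of the sperm difference. Brequinar libraries reached 0.0192% at most. Against the shared DMSO libraries, 333 genes changed the same way with both compounds and 791 opposite ways, against 553.3 opposite for independent lists. Most of the opposite genes, 651, were higher with BAY2402234 and lower with brequinar, and 140 were lower and higher. Genes higher with both numbered 227, more than the 177.1 of independent lists, and genes lower with both 106, against 379. The fold changes had a Pearson correlation of -0.017 and a Spearman correlation of -0.117 across genes, with a covariance of -0.00729 against 0.0525 simulated with no effect. With the controls split 2 and 2 the Pearson correlation was -0.074. Without DMSO replicates 1 to 4 in turn it was 0.014, 0.081, 0.019 and 0.093. The noise of fewer shared controls adds more to the correlation, so these values cannot decide its sign. Without BAY2402234 replicate 1 the correlation was 0.185 and without brequinar replicate 2 it was 0.044, so its sign is not settled. The stricter filter gave 5920 genes.

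The compounds were also compared with the knockdown of their target. BAY2402234 and dhod-1 RNAi differed in 6677 genes by edgeR, 2974 higher and 3703 lower with BAY2402234. Endoplasmic reticulum stress genes were lower with BAY2402234 in 13 of 17 cases (14 adjusted over the list alone, camera adjusted p = 0.0322 with an estimated correlation), and DAF-16 targets were higher in 11 of 13 (11 adjusted over the list alone, camera adjusted p = 0.0113 with an estimated correlation). acs-2, an acyl-CoA synthetase gene, was higher by 4.69 (SE 0.35, edgeR adjusted p = 1.21e-08), and the desaturase gene fat-7 lower by -3.68 (SE 0.29, edgeR adjusted p = 1.04e-08). Sperm genes were higher with BAY2402234 in 49 of 52 cases and lower in 1 (49 and 1 adjusted over the list alone, adjusted p = 0.48 with an estimated correlation). Neuron genes were higher in 38 of 68 and lower in 5 (40 and 5 adjusted over the list alone, adjusted p = 0.56 with an estimated correlation), and muscle genes higher in 16 of 23 and lower in 1 (16 and 1 adjusted over the list alone, adjusted p = 0.475 with an estimated correlation). The sperm share of BAY2402234 replicate 1, 0.0975%, stood apart from the 0.0196% to 0.0235% of the other 3. The dhod-1 RNAi libraries reached 0.00698% at most. Brequinar and dhod-1 RNAi differed in 9739 genes, 4226 higher and 5513 lower with brequinar (136 and 3083 by at least 2-fold). The median of all genes was -0.141. irg-5 was higher with brequinar by 3.28 (SE 0.25, edgeR adjusted p = 8.04e-08) and dpy-14 lower by -3.28 (SE 0.51, edgeR adjusted p = 2.72e-05). Proteasome genes were higher with brequinar in 33 of 33 cases (33 adjusted over the list alone, adjusted p = 0.477 with an estimated correlation). Germ line genes were higher too, 35 of 38 with 0 lower (35 and 0 adjusted over the list alone, adjusted p = 0.48 with an estimated correlation), and intestine genes lower in 13 of 18 with 1 higher (14 and 1 adjusted over the list alone, adjusted p = 0.48 with an estimated correlation). Molting larva genes were lower in 10 of 15 with 1 higher (10 and 1 adjusted over the list alone, camera adjusted p = 0.546 with an estimated correlation). Neuron genes were lower in 20 of 68 with 1 higher (11 and 0 adjusted over the list alone, 0.881 by the same test). Sperm genes were higher in 11 of 52 with 3 lower (1 and 2 adjusted over the list alone, 0.815 by the same test). Against DMSO, fold changes with dhod-1 RNAi correlated across genes at Pearson 0.471 and Spearman 0.524 with those of BAY2402234 (covariance 0.346) and at 0.595 and 0.402 with those of brequinar (covariance 0.419). The simulated values with no effect were 0.501 and a covariance of 0.0525, and with the controls split 2 and 2 the Pearson correlations were 0.398 and 0.5. Genes raised by both BAY2402234 and dhod-1 RNAi numbered 2300, and genes lowered by both 2433, against 1100.2 and 1075 for independent lists. For brequinar these numbers were 515 and 552 against 238.2 and 484.4. With only the groups compared in the fit BAY2402234 and dhod-1 RNAi differed in 4325 genes, and with RNAi replicates 1 and 2 alone, chosen after seeing the data, brequinar and dhod-1 RNAi differed in 5941.

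**Figure D3:**
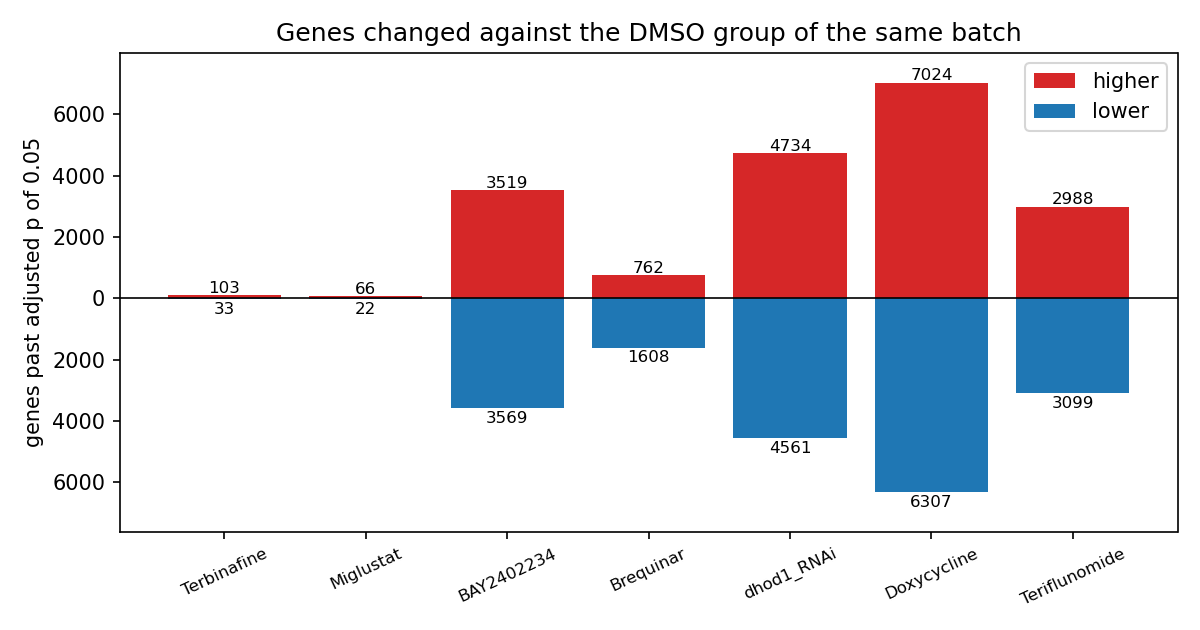
Number of genes higher and lower than DMSO of the same batch in each of 7 comparisons (edgeR quasi-likelihood test, adjusted p below 0.05), with the counts printed at the bars. The totals run from 88 genes with miglustat to 13331 with doxycycline.

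Doxycycline changed most genes tested, 13331 of 15695 by edgeR, 7024 higher and 6307 lower (5360 and 4767 by at least 2-fold). The median of all genes was 0.233, and 0.116 with DESeq2's size factors, so log2 changes below that shift have no fixed sign. Genes of the germ line and of embryos fell furthest. cav-1, a caveolin gene (chromosome IV, 9772510 to 9773559), fell from 224.1 ± 93.3 to 0.134 ± 0.106 CPM (-10.64, SE 0.53, edgeR adjusted p = 3.07e-09), and dpy-14 from 278.4 ± 165 to 0.258 ± 0.082 CPM (-10.05, SE 0.72, edgeR adjusted p = 1.18e-07). hch-1 had 0 counts in all 4 doxycycline libraries and was at least 1040-fold lower, against a floor of 3 counts over the group, and pes-2.1, btb-11 and C08F1.10 were at least 282-fold, 204-fold and 526-fold lower on the same floor. parg-2, a poly(ADP-ribose) glycohydrolase gene, rose from 2.08 ± 1.44 to 102.4 ± 7.14 CPM (5.62, SE 0.44, edgeR adjusted p = 2.19e-07), nhx-6, a sodium/proton exchanger gene, by 5.68 (SE 0.49, edgeR adjusted p = 4e-07) and C07G1.7 by 7.23 (SE 0.48, edgeR adjusted p = 2.88e-08). dct-19 had 2 counts in DMSO, and its ratio was 324 (95% counting interval 89.3 to 2680).

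Respiratory chain genes of both genomes rose with doxycycline. Germ line genes fell and muscle, neuron and intestine genes rose in the same comparison. The rises given here therefore cannot be told from a change in tissue makeup. All 10 mitochondrial DNA genes tested rose (10 adjusted over the list alone, median 1.31, adjusted p = 0.673 with an estimated correlation), atp-6 by 1.63 (SE 0.19, edgeR adjusted p = 6.2e-06), and they took 1.18% ± 0.215 of the counts against 0.514% ± 0.127 in DMSO. Of 48 nuclear-encoded oxidative phosphorylation genes, 43 rose and 5 fell (43 and 5 adjusted over the list alone, median 0.72, adjusted p = 0.599 with an estimated correlation). hsp-6 rose by 0.67 (SE 0.07, edgeR adjusted p = 3.36e-06), and hsp-60 stood at -0.12 (SE 0.14, edgeR adjusted p = 0.427). Of 20 mitochondrial unfolded protein response genes, 7 rose and 7 fell (7 and 7 adjusted over the list alone, camera adjusted p = 0.419). gst-4, a reporter of the SKN-1 response, rose from 8.66 ± 5.29 to 38.8 ± 6 CPM (2.16, SE 0.38, edgeR adjusted p = 0.000207). Of 26 antioxidant and SKN-1 genes, 12 rose and 8 fell (12 and 8 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.159). Hypoxia and sulfide genes rose in 12 of 13 cases (12 adjusted over the list alone, adjusted p = 0.512 with an estimated correlation), among them hif-1 by 1.11 (SE 0.06, edgeR adjusted p = 7.29e-09).

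Germ line genes fell with doxycycline in 37 of 38 cases (37 adjusted over the list alone, median -3.70, adjusted p = 0.487 with an estimated correlation). They took 0.282% ± 0.0347 of the counts against 2.29% ± 0.247 in DMSO, and glp-1, the germ line Notch receptor gene, fell by -2.88 (SE 0.09, edgeR adjusted p = 8.85e-11). DNA damage response genes fell in 16 of 16 cases (16 adjusted over the list alone, median -2.29, adjusted p = 0.512 with an estimated correlation), and proteasome genes in 32 of 33 (32 adjusted over the list alone, median -1.21, adjusted p = 0.559 with an estimated correlation). Of 17 pyrimidine genes, 10 fell and 6 rose (10 and 6 adjusted over the list alone, median -0.60), and the list did not pass (camera adjusted p = 0.28). The ribonucleotide reductase genes rnr-1 and rnr-2 fell by -3.57 and -3.51 (edgeR adjusted p = 1.41e-10 and 1.67e-10). Of 24 zygotic embryo genes, 17 fell and 5 rose (17 and 5 adjusted over the list alone, median -6.27, or -5.63 with 8 genes at their bound, adjusted p = 0.631 with an estimated correlation). Muscle genes rose in 22 of 23 cases with 1 lower (22 and 1 adjusted over the list alone, median 1.73, adjusted p = 0.559 with an estimated correlation). Cuticle collagen genes rose in 104 of 140 with 13 lower (104 and 13 adjusted over the list alone, adjusted p = 0.713 with an estimated correlation). Neuron genes rose in 61 of 72 with 5 lower (61 and 5 adjusted over the list alone, adjusted p = 0.569 with an estimated correlation). Intestine genes rose in 15 of 18 with 2 lower (15 and 2 adjusted over the list alone, adjusted p = 0.059 with an estimated correlation). Sperm genes rose in 38 of 56 cases (32 adjusted over the list alone, adjusted p = 0.818 with an estimated correlation). Their share was 0.2235% to 0.3818% with doxycycline. It was 0.278% in DMSO replicate 1 and 0.034% to 0.0395% in the other 3.

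Teriflunomide changed 6087 genes by edgeR, 2988 higher and 3099 lower (1469 and 1482 by at least 2-fold), and genes of drug metabolism rose furthest. cyp-13A6 (chromosome II, 9800758 to 9802821) rose from 0.438 ± 0.274 to 1472 ± 140 CPM (11.70, SE 0.29, edgeR adjusted p = 3.2e-10) and cyp-13A12 from 0.596 ± 0.217 to 985.7 ± 155 CPM (10.68, SE 0.21, edgeR adjusted p = 4.55e-11). The glucuronosyltransferase gene ugt-19 rose from 2.42 ± 0.784 to 901.5 ± 124 CPM (8.54, SE 0.27, edgeR adjusted p = 1.9e-09) and gst-8 from 0.187 ± 0.0949 to 141.9 ± 10.6 CPM (9.52, SE 0.22, edgeR adjusted p = 1.48e-10). cyp-13A6 lies in a cluster of similar copies on chromosome II, so its single value is uncertain. acdh-2 had 0 counts with teriflunomide and was at least 352-fold lower against a floor of 3 counts over the group. sysm-1 and dod-22, both of the immune list, fell by -8.63 (SE 0.93, edgeR adjusted p = 5.5e-05) and -7.14 (SE 0.81, edgeR adjusted p = 8.36e-05), and pho-11, an acid phosphatase gene, from 144.4 ± 25.5 to 1.98 ± 0.488 CPM (-6.19, SE 0.19, edgeR adjusted p = 1.48e-09).

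Of 166 xenobiotic enzyme genes, 94 rose and 16 fell with teriflunomide (99 and 17 adjusted over the list alone, camera adjusted p = 0.0343 with an estimated correlation). Of 26 antioxidant and SKN-1 genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 0.0264 with an estimated correlation), gst-5 by 5.50 (SE 0.12, edgeR adjusted p = 1.46e-10). Fatty acid oxidation genes rose in 16 of 35 cases and fell in 6 (16 and 8 adjusted over the list alone, camera adjusted p = 0.0343 with an estimated correlation). They include daf-22 and dhs-28 of peroxisomal beta-oxidation at 2.46 and 1.82 (edgeR adjusted p = 1.12e-09 and 1.9e-09). Intestine genes rose in 12 of 18 (12 adjusted over the list alone, camera adjusted p = 0.0343 with an estimated correlation). Immune genes fell in 15 of 29 with 4 higher (15 and 5 adjusted over the list alone, adjusted p = 0.559 with an estimated correlation). Of 24 zygotic embryo genes, 14 fell and 3 rose (15 and 4 adjusted over the list alone, median -2.34, adjusted p = 0.559 with an estimated correlation). Molting larva genes fell in 10 of 16 with 2 higher (10 and 2 adjusted over the list alone, median -1.85, adjusted p = 0.599 with an estimated correlation). Sperm genes rose in 13 of 56 with 1 lower (1 and 0 adjusted over the list alone, median 1.51, adjusted p = 0.734 with an estimated correlation). Muscle genes rose in 21 of 23 with 1 lower (21 and 1 adjusted over the list alone, adjusted p = 0.559 with an estimated correlation), and nuclear-encoded oxidative phosphorylation genes in 42 of 48 with 2 lower (42 and 2 adjusted over the list alone, median 0.38, adjusted p = 0.576 with an estimated correlation). hsp-6 rose by 0.51 (SE 0.07, edgeR adjusted p = 0.000285), hsp-4 from 514.5 ± 173 to 998.8 ± 126 CPM (0.96, SE 0.19, edgeR adjusted p = 0.00246) and hsp-16.2 by 2.16 (SE 0.33, edgeR adjusted p = 0.000486). Of 17 endoplasmic reticulum stress genes, 13 rose and 2 fell (13 and 2 adjusted over the list alone, adjusted p = 0.559 with an estimated correlation), and of 16 cytosolic heat shock genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone, adjusted p = 0.582 with an estimated correlation). Of 20 mitochondrial unfolded protein response genes, 14 rose and 0 fell (14 and 2 adjusted over the list alone, adjusted p = 0.559 with an estimated correlation). For the list mitochondrial UPR in Teriflunomide vs DMSO_batch2, the call by camera of limma, adjusted p = 0.045, was lost without DMSO replicates 1, 2 or 4 (0.235, 0.0609 and 0.0714) or teriflunomide replicates 2 or 4 (0.0541 and 0.0551). Yolk genes took 3.46% ± 0.385 of the counts against 6.40% ± 0.479 in DMSO, and sperm genes 0.26% ± 0.0357 against 0.0974% ± 0.12. Of 6 yolk genes, 4 fell and 0 rose (4 and 0 adjusted over the list alone, adjusted p = 0.559 with an estimated correlation), and the call for the list vitellogenins in Teriflunomide vs DMSO_batch2, camera adjusted p = 0.0119 by limma, was lost without DMSO replicate 1 (0.063). The sperm share was 0.278% in DMSO replicate 1 and between 0.034% and 0.0395% in the other 3, so that replicate alone carries the spread and most of the DMSO mean. Without DMSO replicate 1, the library that stood apart, edgeR called 9148 genes, 4924 higher and 4224 lower. The median of all genes was -0.0162, and -0.0915 with DESeq2's size factors.

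Teriflunomide and brequinar were given in different batches and at different doses, 250 and 500 µM, so each was set against its own DMSO and the difference of the effects was tested in one fit with batch as a term. By edgeR the effects differed in 7272 of 15244 genes, 3590 higher and 3682 lower with teriflunomide. ugt-19 differed by 7.91 (SE 0.43, edgeR adjusted p = 3.05e-08), gst-8 by 8.80 (SE 0.75, edgeR adjusted p = 1.3e-06) and irg-5 by -6.35 (SE 0.58, edgeR adjusted p = 5.03e-06). For teriflunomide minus BAY2402234 the count was 5843 of 15554, 2522 higher and 3321 lower, with cyp-13A12 at 9.81 (SE 0.69, edgeR adjusted p = 2.17e-07), dod-22 at -9.62 (SE 0.95, edgeR adjusted p = 9.03e-06) and sysm-1 at -10.77 (SE 1.06, edgeR adjusted p = 9.19e-06). Antioxidant and SKN-1 genes were higher with teriflunomide in both differences, 12 of 25 with 1 lower against brequinar (12 and 1 adjusted over the list alone) and 13 of 25 with 1 lower against BAY2402234 (13 and 1 adjusted over the list alone), with camera adjusted p = 0.0274 and 0.00269 with an estimated correlation. Mitochondrial unfolded protein response genes were higher with teriflunomide than with BAY2402234 in 16 of 20 cases and lower in 1 (16 and 1 adjusted over the list alone, adjusted p = 0.139 with an estimated correlation). Against brequinar 8 of the 20 were higher and 2 lower (8 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0976). Tissue markers differed from brequinar. Sperm genes were higher with teriflunomide in 49 of 55 cases (51 adjusted over the list alone, median 3.22, adjusted p = 0.514 with an estimated correlation), muscle genes in 22 of 23 with 1 lower (22 and 1 adjusted over the list alone, median 1.54, adjusted p = 0.188 with an estimated correlation) and intestine genes in 13 of 18 (14 adjusted over the list alone, adjusted p = 0.139 with an estimated correlation). Neuron genes were higher in 33 of 68 and lower in 4 (33 and 4 adjusted over the list alone, adjusted p = 0.556 with an estimated correlation). Zygotic embryo genes were lower in 28 of 36 and higher in 4 (28 and 4 adjusted over the list alone, median -2.92, adjusted p = 0.182 with an estimated correlation), and molting larva genes lower in 11 of 15 and higher in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.269 with an estimated correlation). Germ line genes were lower in 11 of 38 (5 adjusted over the list alone, median -0.21, adjusted p = 0.638 with an estimated correlation). Against BAY2402234, zygotic embryo genes were lower with teriflunomide in 27 of 36 and higher in 2 (28 and 2 adjusted over the list alone, median -2.57, adjusted p = 0.212 with an estimated correlation). Molting larva genes were lower in 10 of 15 and higher in 1 (10 and 1 adjusted over the list alone, median -2.83, adjusted p = 0.188 with an estimated correlation). Muscle genes were higher in 16 of 23 and lower in 1 (18 and 1 adjusted over the list alone, adjusted p = 0.409 with an estimated correlation), and germ line genes higher in 13 of 38 (13 adjusted over the list alone, adjusted p = 0.579 with an estimated correlation). Of 55 sperm genes, 1 was higher and 1 lower (0 and 0 adjusted over the list alone, median 1.41, adjusted p = 0.638 with an estimated correlation). Across genes the fold changes of teriflunomide, which share no controls with the others, correlated with those of brequinar at Pearson -0.264 and Spearman -0.409 and with those of BAY2402234 at -0.066 and 0.029.

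The DMSO groups of the batches received the same solvent, and 3633 of 14093 genes, or 25.8%, differed between them by edgeR, 2108 higher and 1525 lower in batch 2. The collagen gene col-165 was higher by 10.11 (SE 1.03, edgeR adjusted p = 0.00102) and the histone gene hil-7 by 7.19 (SE 0.55, edgeR adjusted p = 0.000494), while the transporter gene pgp-8 was lower, at 0.528 ± 0.18 against 29.6 ± 2.64 CPM (-5.80, SE 0.24, edgeR adjusted p = 2.38e-05) and cyp-35A3 by -5.31 (SE 0.32, edgeR adjusted p = 0.000129). In this comparison the batch cannot be told apart from anything else that differed between the rounds of culture. The stricter filter gave 1986 genes, and edgeR called 2307 and 2220 without DMSO replicates 2 and 3 of batch 1 and 2246 without replicate 2 of batch 2.

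**Figure D4:**
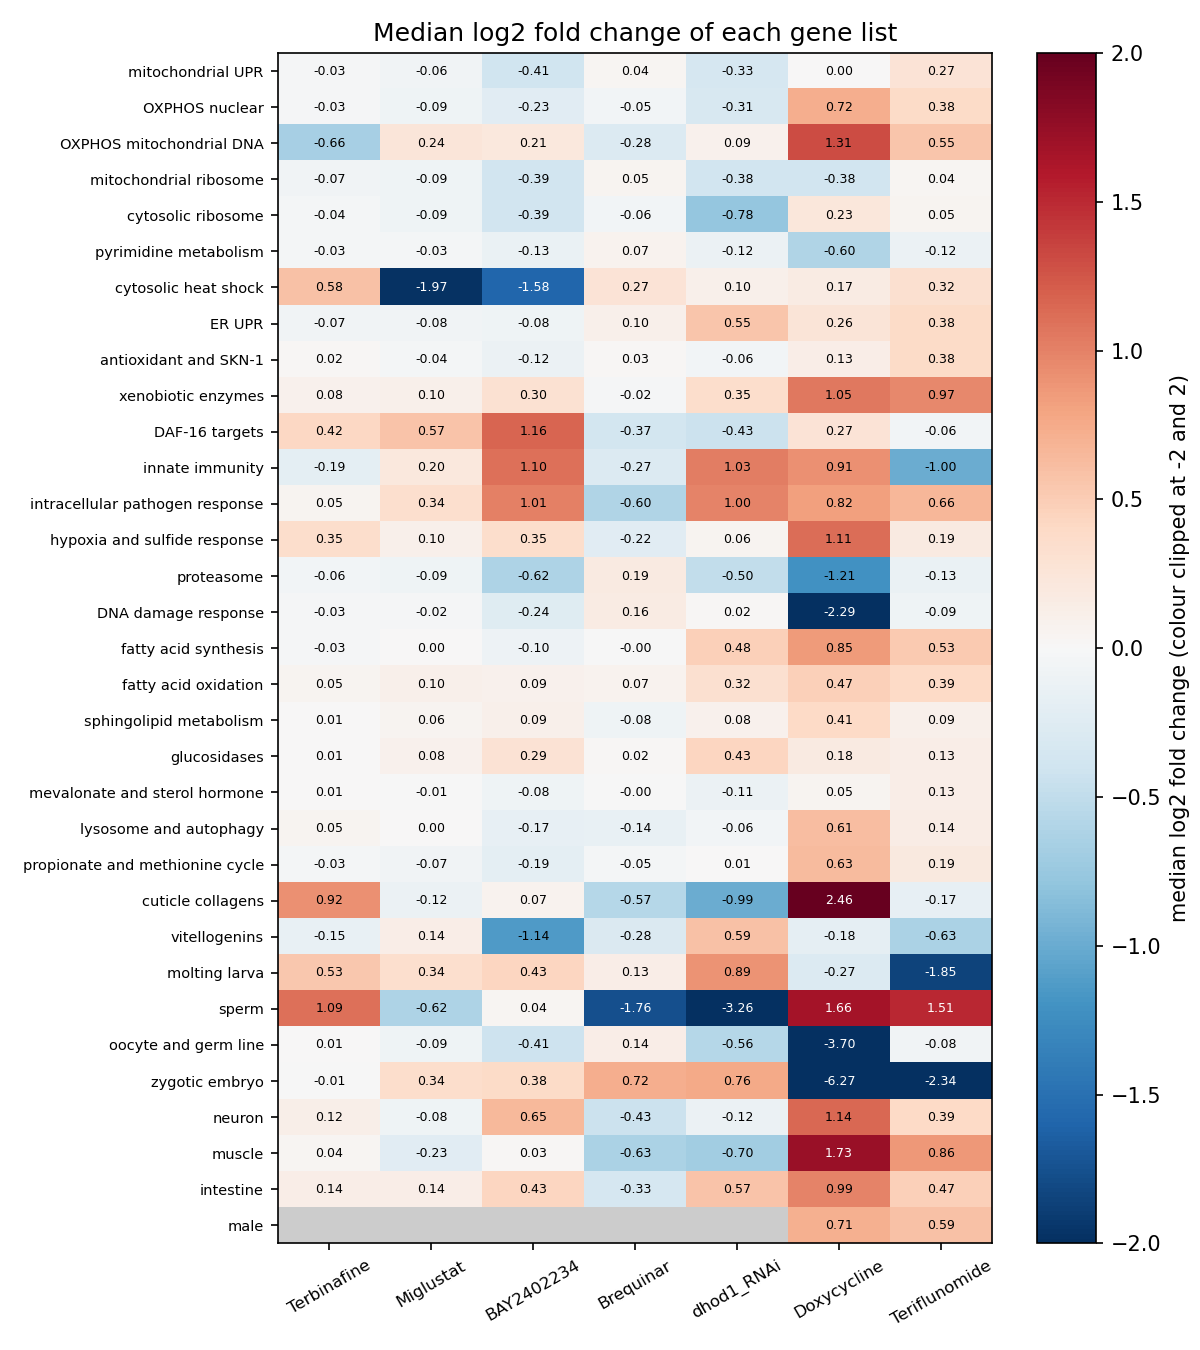
Median log2 fold change of each of 33 gene lists in the 7 comparisons with DMSO, colour clipped at -2 and 2 with the median printed in each cell; the male list was tested in batch 2 only. The doxycycline median of -6.27 for zygotic embryo genes is -5.63 with 8 genes at their bound, and cytosolic heat shock genes have medians of -1.97 with miglustat and -1.58 with BAY2402234.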

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

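Some tests below were chosen only after the result was seen, namely scaling and held embryos for doxycycline, the difference in depth for BAY2402234 and brequinar, the count of opposite calls without each control library, both tests for cyp-35B, and the splits of the DMSO groups; predictions for the others were written first.

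With doxycycline, germ line genes fell while muscle, collagen and neuron genes rose. Scaling alone would move all genes alike, whereas the muscle median minus the germ line median was 5.43. Scaling therefore does not account for the gap between these lists. That gap restates the pattern, so the value does not show which of the lists changed per worm. The comparison of medians replaced an earlier test that could not tell the causes apart. Fewer germ cells per worm would lower germ line genes outside the list, and 60 such genes had a median of -2.12 (quartiles -2.76 to -1.46), with 53 lower and 4 higher. The 7 genes that act before fertilization had a median of -1.79 (-2.65 to -0.08). Loss of embryos held in the control worms would spare them only if embryos carried none of their transcripts, which was not tested. Held embryos are therefore not excluded. The falls would follow from fewer germ cells, but neither set of genes separates this from fewer embryos. Sperm genes, also of germ cells, took 0.293% ± 0.069 of the counts with doxycycline against 0.0974% ± 0.12 in DMSO. DMSO replicate 1, at 0.278%, lay within the doxycycline range of 0.2235% to 0.3818%, and the other 3 at 0.034% to 0.0395%. Yolk genes took 6.02% ± 0.927 of the counts with doxycycline against 6.40% ± 0.479 in DMSO. A change within each germ cell and a difference in stage were not tested.

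BAY2402234 and brequinar, given for the same target, moved 791 genes in opposite directions, 651 of them higher with BAY2402234. Given the doxycycline response, taken as an axis of stage or tissue makeup, the partial correlation was 0.015 against a plain one of -0.097 over 14435 genes. The value met the bound written for this cause, but the jackknife SD over 12 libraries, 0.211, exceeds the gap between the bounds, so the test cannot tell. The total counts overlap (gap of -517407 reads), which argues against depth. The correlation of -0.017 turned to between 0.014 and 0.093 without any 1 DMSO library. The noise of fewer shared controls adds to it, and the band of 0.3 written for this test spans both signs, so the test decides nothing. Opposite calls, in contrast, stayed at 1.47 to 1.94 times those of independent lists (SD 0.244), so 1 control library does not carry them.

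The cyp-35B genes were far higher with terbinafine. Reads of 1 gene shared among copies would keep cyp-35B2 and cyp-35B3 in a fixed ratio, and the chi-square per degree of freedom of their counts was 129. It was 1.8 without terbinafine replicate 4 (ratio 1.52, others 1.11 to 1.15), so the test cannot tell. Mixing with another sample of the series does not account for the high values. The highest mean of cyp-35B3 elsewhere in the series was 0.235 CPM, in miglustat, against 450 CPM with terbinafine, both scaled by total counts. Mixing with a sample from outside the series was not tested. No biological explanation was tested for these genes.

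Regrouping the 8 libraries of each comparison of 4 against 4 gave 35 splits each, and in all 12 comparisons 1 split, the real one, reached its count. The highest other counts were 4973 for dhod-1 RNAi, 4117 for teriflunomide, 86 for terbinafine against miglustat, 3094 for BAY2402234 against dhod-1 RNAi and 6669 for brequinar against dhod-1 RNAi, and at most 4 elsewhere. For the 2 differences of effects, which rest on 16 libraries, only the 8 libraries of the compounds were regrouped; 1 of 35 splits, the real one, reached 7272 and 5843 genes and the others 0, but as the other splits also mix the batches, chance is not excluded by this.

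Of 120 groups of values tested by Dixon's rule, in which chance picks about 1 in 20, 6 had a library far from the other 3. gst-4 stood at 4.22 CPM in miglustat replicate 2 (others 8.79 to 9.51). hsp-60 stood at 297.6 CPM in teriflunomide replicate 1 (others 373.5 to 386.4). Sperm genes took 0.0975% in BAY2402234 replicate 1 (others 0.0196% to 0.0235%). Germ line genes took 2.62% in replicate 2 of the batch 1 DMSO group (others 2.49% to 2.50%). In replicate 1 of the batch 2 DMSO group, sperm genes took 0.278% (others 0.034% to 0.0395%) and mitochondrial DNA genes 0.703% (others 0.435% to 0.473%).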

How the results depend on the processing

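Every alternative that was planned was run. No call for a gene or list turned its direction. The correlation of BAY2402234 with brequinar, -0.017, ranged from -0.081 to 0.185 and was positive without any 1 DMSO library. Leaving out a shared control adds to such a correlation by itself. The correlation of terbinafine with miglustat, 0.112, ranged from -0.066 to 0.288. With teriflunomide 2988 genes were higher and 3099 lower, and without replicate 1 of its DMSO group 4924 and 4224. With at least a 2-fold change required, which by construction keeps a subset, the counts were 80 (terbinafine), 51 (miglustat), 1640 (BAY2402234), 883 (brequinar), 3418 (dhod-1 RNAi), 2951 (teriflunomide), 261 (terbinafine against miglustat), 3332 (BAY2402234 against brequinar), 2841 and 3219 (BAY2402234 and brequinar against dhod-1 RNAi), 4185 and 3212 (teriflunomide minus brequinar and minus BAY2402234) and 1700 (DMSO groups). DESeq2 gave 243 (terbinafine), 270 (miglustat) and 863 (terbinafine against miglustat). The stricter filter gave 51 (miglustat), 246 (terbinafine against miglustat), 5920 (BAY2402234 against brequinar) and 1986 (DMSO groups). With only the groups compared in the fit the counts were 39 (miglustat), 3749 (brequinar) and 4325 (BAY2402234 against dhod-1 RNAi). The labels do not say that a replicate number marks a shared day or batch. Libraries of the same number deviated together in some groups of batch 1, as for BAY2402234 and brequinar (0.637, 0.297, -0.04 and 0.447). Of 60 such pairs, 27 had a correlation over 0.1 (median 0.0634, range -0.641 to 0.688). Of 24 libraries, 12 fitted best with their own number, above the 1 in 4 of a random pick, so a factor shared by number is left open in batch 1. In batch 2 these were 2 of 12 pairs (median -0.152) and 0 of 12 libraries. The replicate block gave 822 genes in place of 448 for terbinafine against miglustat and moved no other count by over 1.5 times. Replicates 1 and 2 of dhod-1 RNAi alone, chosen after seeing the data, gave 5132 against DMSO and 5941 for brequinar against dhod-1 RNAi. With an estimated correlation 8 of 226 list tests against DMSO passed in place of 125. By fry, which asks a different question, 177 of the 226 results stayed the same, 31 calls were lost and 18 gained. Apart from the fold requirement, the cause was not tested.

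Leaving out 1 library at a time gave 76 to 172 genes for terbinafine, 22 to 254 for miglustat, 1154 to 2541 for brequinar, 4596 to 9148 for teriflunomide, 213 to 444 for terbinafine against miglustat and 2220 to 4790 for the DMSO groups. The other counts stayed within 1.5 times. dhod-1 in its RNAi group ranged from -0.35 to -0.21. Of the calls for named genes, 383 were lost and 43 gained as libraries were left out and 8566 stayed, and of those for single lists 89 were lost, 31 gained and 1688 stayed. Depth limits genes with 3 counts or fewer in a group, for which only a ratio with an interval or a bound could be given.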

Other observations

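No further tests were chosen after the result was seen for the values below, and no explanation was tested for them.

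Miglustat and BAY2402234 shared changes although their targets differ. Of the genes changed by both, 60 were higher and 20 lower with each, against 15.3 and 5.2 for independent lists, and 1 moved opposite ways. The fold changes correlated at Pearson 0.547 and Spearman 0.507 across genes (covariance 0.135). Groups simulated with no effect gave a Pearson correlation of 0.501 and a covariance of 0.0525 from the shared controls, and the observed correlation was 0.331 with the controls split 2 and 2.

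Brequinar and doxycycline share no controls, and their fold changes ran opposite ways, with a Pearson correlation of -0.507 and a Spearman correlation of -0.617. Genes changed by both numbered 155 in the same and 1884 in opposite directions, against 992.7 opposite for independent lists.

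Doxycycline and teriflunomide share the DMSO libraries of batch 2, of which replicate 1 stands apart. Both raised 2607 genes and both lowered 2244, against 1337.2 and 1245.3 for independent lists, and 381 moved opposite ways, against 2587.6. The Pearson correlation was 0.55 against 0.497 simulated with no effect, the Spearman correlation was 0.645, the covariance was 1.34 against 0.0619, and with the controls split 2 and 2 the Pearson correlation was 0.493.

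With doxycycline, 19 of 23 genes of propionate breakdown and the methionine cycle rose and 2 fell (20 and 2 adjusted over the list alone, camera adjusted p = 0.0317), and adjusted p = 0.677 with an estimated correlation. pcca-1, a propionyl-CoA carboxylase gene, rose by 0.99 (SE 0.07, edgeR adjusted p = 4.63e-08), and sams-3, an S-adenosylmethionine synthetase gene, fell from 109.6 ± 2.93 to 26.9 ± 3.62 CPM (edgeR adjusted p = 4.83e-10).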
